A study of Mus musculus with 13 samples.

How the data were processed

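RNA was measured by sequencing in 13 libraries of mouse colon tumour organoids carrying an activating Kras allele and an inactivating Apc allele, in the C57BL/6 strain. Per the labels' protocols, Cas9 and then a guide RNA against Brd4 or a non-targeting guide RNA were brought in by lentivirus, organoids in Matrigel were dissolved in ISOGEN, and libraries were made with the NEBNext Ultra II RNA kit. There were 4 control libraries (non-targeting guide), 3 Brd4 knockout libraries, 3 control libraries with IFNg and 3 Brd4 knockout libraries with IFNg. The dose and duration of IFNg are not given in the sources used here.

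The deposited table holds, per the file headers, gene-level RSEM values in CPM (counts per 1e6 reads) with an Ensembl identifier, a gene name, a biotype and a position for each gene. Per the submitters' processing notes, Trim Galore 0.6.7, cutadapt 3.5, STAR 2.7.7a and 2.7.10a and RSEM 1.3.1 were used with build GRCm39; which library went through which STAR version, and in what order, is not stated. The table holds 55322 genes on 21 chromosomes, 27458 of them above 0 in at least 1 library, and all 13 value columns were used. No gene of the mitochondrial genome is listed, so the fixed list of mitochondrially encoded genes had no member to test. Gene positions and names were taken from the table; 52046 identifiers also matched the reference names given for use here, whose build is older, and no position was taken from it.

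Each CPM value that the authors deposited was a whole multiple of its column's smallest value, and whole reads, within 0.001 of a read, were recovered for 100% of the values. The denominators so recovered, 15.0 to 64.5 M reads (M for 1e6), exceed the reads in the listed genes, 8.5 to 37.4 M. By group, the reads in listed genes ran from 8.5 to 12.6 M in control, 25.9 to 33.5 M in the knockout, 12.9 to 37.4 M in control with IFNg and 14.7 to 20.2 M in the knockout with IFNg. The share of the denominator outside the listed genes was 43.5 ± 0.75% in control (SD, n = 4), 36.3 ± 0.896% in the knockout (SD, n = 3), 37.9 ± 3.85% in control with IFNg (SD, n = 3) and 30.9 ± 2.79% in the knockout with IFNg (SD, n = 3). What those other reads are is not given in the sources used here. A single read was worth 0.0155 to 0.0666 CPM.

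Values were used as deposited and put on a log2 scale after adding 1 CPM. A fold on this scale understates the change of genes near or under 1 CPM. Genes with at least 1 CPM in at least 3 libraries were tested, 12849 in all. The 4 groups were fitted together with limma 3.58.1 in R 4.3.3 (linear model, empirical Bayes moderation with an intensity trend, 9 residual degrees of freedom), and 5 comparisons were drawn from the fit: knockout against control, control with IFNg against control, knockout with IFNg against knockout, knockout with IFNg against control with IFNg, and the interaction, which is the IFNg response in the knockout minus that in control. P-values were adjusted by Benjamini and Hochberg within each comparison, and an adjusted p under 0.05 counted as a change. Every adjusted p of a gene given below is from limma unless edgeR is named. Errors beside log2 fold changes are limma's standard errors.

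Gene groups were 32 lists fixed before the data were examined. The 27 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with a correlation estimated from the data. Members were also adjusted over the list alone. The lists, with measured genes of those fixed, were IFNg response core (33 of 33), type I interferon-associated genes (30 of 33), MHC class I and antigen processing (22 of 23), MHC class II (11 of 12), IFNg receptor and JAK-STAT components (18 of 18), pro-apoptotic (29 of 30), anti-apoptotic (15 of 19), pyroptosis and necroptosis (21 of 29), intestinal stem cell (18 of 21), Wnt target (20 of 23), fetal-like and YAP-associated (19 of 23), absorptive colonocyte (14 of 28), goblet (5 of 18), enteroendocrine (1 of 21), tuft (3 of 17), Paneth and deep crypt secretory (6 of 16), proliferation (32 of 32), MYC and ribosome biogenesis (27 of 28), BET proteins and P-TEFb (17 of 18), NF-kB and inflammatory chemokines (22 of 30), p53 targets (23 of 23), integrated stress and unfolded protein response (23 of 24), hypoxia and glycolysis (23 of 25), KRAS-ERK output (25 of 25), cholesterol biosynthesis (25 of 25), nuclear-encoded oxidative phosphorylation (27 of 30), epithelial junction and adhesion (22 of 24), stromal (2 of 19), immune (2 of 21), mitochondrially encoded (0 of 15), cytosolic ribosomal proteins (31 of 31) and replication-dependent histones (20 of 25).

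The genes named were chosen by a rule fixed with the lists. It takes 12 genes always (Brd4, Myc, Stat1, Irf1, Ifngr1, Ifngr2, Jak1, Jak2, Casp8, Cd274, Cxcl10 and Ido1). It adds the 8 higher and 8 lower genes of each comparison, 6 and 6 for the interaction, with the largest fold change among those past the threshold with a mean of at least 5 CPM and, for 2 groups, no overlap between their libraries; names of unnamed gene models were skipped. It adds up to 4 members of each list with the largest change past the threshold, or the member with the smallest p where none passed. Other genes are marked as chosen after their values were seen. Where every library of a group was at 0, no fitted fold against it is given in a comparison of 2 groups. A fitted interaction value of such a gene is no bound, since its size rests on the added 1 CPM. A lower bound of the fold is given instead, taking the group at 3 reads over all its libraries, which is 0.042 CPM in control, 0.0217 in the knockout, 0.0264 in control with IFNg and 0.04 in the knockout with IFNg. Those floors cover counting error only.

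Replicate numbers were checked as pairs and were not used in the fit: over 18 pairs of libraries with the same number, residual correlations ran from −0.12 to 0.121, with 2 over 0.1. No 2 libraries of a group were duplicates; a chi-square per degree of freedom between their reads was 16.6 to 193 over 15 pairs. The alternatives tried were a pseudocount of 0.25, no filter, a mean of at least 5 CPM, median-of-ratios rescaling, quantile normalization, a fit of only the groups compared, the replicate number as a block, limma's array weights, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the estimated correlation, and leaving out each library in turn. Added after the data were seen were thinning of the reads to the smallest library's 8494083, scaling to the listed genes without the ribosomal RNA gene Rn18s, and leaving out library 3 of control with IFNg and library 1 of the knockout with IFNg together. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

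The fit was tested on simulated data with 200 changed genes, and a list of 30 more changed ones, among 12420 to 12451 tested. How many genes near 1 CPM would be recovered was not tested. Of 100 genes changed 4-fold, 85%, 83%, 84%, 83% and 36% were recovered in the order of the comparisons above. Of 100 genes changed 2-fold, 26%, 30%, 36%, 30% and 3% were recovered in the same order. At most 9 unchanged genes were called, 0.074% of those left alone.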

Results

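Organoids are clusters of epithelial cells grown in a gel from tissue stem cells. Those studied here came from mouse colon tumours with an activating Kras allele and an inactivating Apc allele. IFNg is a cytokine of immune cells that acts through its receptor, JAK kinases and the transcription factor STAT1, and it can kill epithelial cells. Brd4 is a BET protein that binds acetylated chromatin and aids transcription, and CRISPR-Cas9 cuts a gene at a guide RNA so that repair can inactivate it. The series concerns Brd4 knockout organoids that partly resist death caused by IFNg. The 13 libraries formed 4 groups: control (n = 4), Brd4 knockout (n = 3), control with IFNg (n = 3) and Brd4 knockout with IFNg (n = 3). They held 8.5 to 37.4 M reads (M for 1e6) in listed genes. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. Cell death itself was not measured in these data.

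Without IFNg the Brd4 transcript did not separate the knockout libraries from control; with IFNg it was lower in the knockout, and the libraries did not overlap. Brd4 (chromosome 17:32415248-32503696 in GRCm39, ENSMUSG00000024002) was at 43.3, 33.2, 40.7 and 32.8 CPM in the control libraries and at 26.7, 35.8 and 40.8 CPM in the knockout libraries. With IFNg it was at 44.0, 50.5 and 53.6 CPM in control and at 26.3, 29.6 and 34.6 CPM in the knockout. Means were 37.5 ± 5.33 and 34.4 ± 7.12 CPM without IFNg (SD, n = 4 and n = 3), a log2 fold change of −0.13 ± 0.21 with an adjusted p = 0.752. They were 49.4 ± 4.87 and 30.2 ± 4.22 CPM with IFNg (SD, n = 3 and n = 3), a log2 fold change of −0.70 ± 0.22 with an adjusted p = 0.0281. The adjusted p was 0.0874 without library 3 of control with IFNg (fold −0.64) and 0.0628 and 0.0742 without library 1 and library 2 of the knockout with IFNg (folds −0.60 and −0.69). A gene cut by CRISPR can still be transcribed, so a level like that of control does not contradict the labels; protein was not analysed here. Of the libraries, 3 stood apart: library 3 of control with IFNg had 9.7% of its listed reads on the 18S ribosomal RNA gene Rn18s, and library 1 of the knockout with IFNg had 7.08%, against 3.01% and 3.02% in the rest of its group. The latter lay at −64.37 on the principal component 4, with 18.07 and 35.37 for the others of its group, and library 2 of control with IFNg at −22.98, with 18.44 and 5.77. Untreated control differed in library make-up: 43.5% of its reads lay outside the listed genes, against 30.9 to 37.9% in the other groups, and 6 mitochondrial-like pseudogenes on chromosome 1, Gm10925 among them, summed to 22609 ± 433 CPM (SD, n = 4), against 9185 to 14277 CPM. No label gives a batch, so one that follows the groups cannot be excluded. Of genes that mark other cells, Ptprc was at most 2.05 CPM and Col1a1 at most 0.212 CPM in any library, but Cd68 reached 49.6 CPM, S100a8 29.2 CPM, Vim 7.48 CPM and the tuft cell gene Avil 105 CPM.

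Without IFNg, the knockout asks which genes differ in resting tumour organoids given the Brd4 guide. Knockout organoids had all but lost the cell cycle inhibitors Cdkn2a and Cdkn2b and the positional gene Hoxa9, and had gained the growth factor Ptn and the LIM protein gene Crip1. Ptn (6:36691864-36787155) rose from 0.0801 ± 0.0704 CPM (SD, n = 4) to 86.7 ± 9.17 CPM (SD, n = 3), and Crip1 from 0.764 ± 0.884 (SD, n = 4) to 183 ± 60.8 CPM (SD, n = 3). Cdkn2b (4:89224536-89229276) fell from 55.3 ± 8.61 CPM (SD, n = 4) to 0.0129 ± 0.0223 CPM (SD, n = 3), Cdkn2a (4:89192708-89212890) from 29.8 ± 13.8 to 0.129 ± 0.0292 CPM, and Hoxa9 from 27.7 to 0.0138 CPM. Ribosomal protein genes rose in 27 of 31 and integrated stress genes in 14 of 23 (adjusted p = 0.232 and adjusted p = 0.279 with an estimated correlation). Of 19 fetal-like genes 7 fell, such as Il33, Gja1 and Ly6d, and 3 rose (adjusted p = 0.218 with an estimated correlation).

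Among 12849 tested genes, 1200 were higher and 728 lower in the knockout, 839 and 553 of them over 2-fold. After median-of-ratios rescaling the split was 1001 higher and 951 lower, so 62.2% of the changed genes were higher on the deposited scale and 51.3% on the rescaled one, and 1728 were shared. The largest rises were in Crip1 (6.80 ± 0.36, adjusted p = 5.21e-10), Ptn (6.34 ± 0.27, adjusted p = 4.11e-11), Lmo2 (5.38 ± 0.57) and Ddah1 (5.29 ± 0.31), and in the hair keratin-associated genes Krtap3-3 (6.39), Krtap3-1 (5.16) and Krtap3-2 (5.12), which resemble each other too closely for reads to be placed with certainty. Krtap13-1 was at 0 in control and rose at least 950-fold. The largest falls were in Wfdc2 (−6.52 ± 0.33, adjusted p = 2.56e-10), Cdkn2b (−5.79 ± 0.29, adjusted p = 2.56e-10), Gmpr (−5.17), Mmp14 (−4.90), Hoxa9 (−4.81 ± 0.32, adjusted p = 7.07e-09), Wfdc18 (−4.77), Cdkn2a (−4.62 ± 0.37, adjusted p = 8.07e-08) and Il33 (−4.57). Of the IFNg pathway, Irf1 fell from 8.6 ± 1.63 to 4.08 ± 1.9 CPM (−0.98 ± 0.28, adjusted p = 0.0205; SD, n = 4 and n = 3), but with adjusted p = 0.138 without library 1 of the knockout (−0.64), 0.0664 without library 3 of control (−0.88) and 0.0764 without a filter (−0.98). Stat1 (−0.60, adjusted p = 0.118), Ifngr1 (0.81, adjusted p = 0.18), Ifngr2 (0.46, adjusted p = 0.106), Jak1 (−0.30, adjusted p = 0.411) and Jak2 (−0.99, adjusted p = 0.0555) did not pass. Nor did Casp8 (−0.29, adjusted p = 0.495), Cd274 (−0.07, adjusted p = 0.946), Cxcl10 (0.22, adjusted p = 0.742), Ido1 (adjusted p = 0.544) or Myc (0.63, adjusted p = 0.0653). The count of higher genes was 781 without library 3 of the knockout. That of lower genes was 462 without its library 2 and 468 without its library 3.

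Ribosomal protein genes rose together: Rpl13 (2.36 ± 0.24, adjusted p = 1.79e-06), Rps2 (1.78), Rpl32 (1.55) and Rplp1 (1.40). Of 31, 27 were higher, 0 lower and 4 not passing, with 28 higher and 0 lower adjusted over the list alone; control also had more reads outside the listed genes, and after rescaling 26 were higher. The median was 0.96 (camera adjusted p = 3.71e-21, and adjusted p = 0.232 with an estimated correlation). Genes of the integrated stress response rose, among them the folate enzyme Mthfd2 (2.13 ± 0.37, adjusted p = 0.000488), from 37.1 to 154 CPM. In that list 14 were higher, 0 lower and 9 not passing, with 16 and 0 adjusted over the list alone. The median was 1.33 (camera adjusted p = 2.6e-06, and adjusted p = 0.279 with an estimated correlation). Replication-dependent histones such as H1f2 (2.52) and H3c3 (3.26) were higher in 10, lower in 0 and not passing in 10, with 11 and 0 adjusted over the list alone. Their median was 0.69 (camera adjusted p = 0.000252, and adjusted p = 0.469 with an estimated correlation). Histone genes are near copies of each other. Of the MHC class II genes, Cd74 rose from 0.208 to 7.42 CPM (2.82 ± 0.20, adjusted p = 1.92e-08) and H2-Eb1 rose (0.98); 3 were higher, 0 lower and 8 not passing, with 6 and 0 adjusted over the list alone. The median was 0.77 (camera adjusted p = 0.0173, and adjusted p = 0.469 with an estimated correlation). The MYC and ribosome biogenesis list moved as a set, with 1 higher, 0 lower and 26 not passing, and 0 and 0 adjusted over the list alone. Its median was 0.44 (camera adjusted p = 0.0148, and adjusted p = 0.724 with an estimated correlation). Without library 3 of the knockout its camera adjusted p = 0.0829.

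Lower as sets were the fetal-like and YAP-associated genes, with Il33, Gja1 (−3.77 ± 0.32, adjusted p = 1.46e-07) and Ly6d (−2.85) falling: 3 were higher, 7 lower and 9 not passing, with 3 and 9 adjusted over the list alone. The median was −0.49 (camera adjusted p = 0.000111, and adjusted p = 0.218 with an estimated correlation). The Paneth and deep crypt secretory list, with Pla2g2a (−2.89) and Mmp7 (−2.71), had 0 higher, 3 lower and 3 not passing, with 0 and 3 adjusted over the list alone. Its median was −0.98 (camera adjusted p = 0.00018, and adjusted p = 0.218 with an estimated correlation). Goblet genes split, Bcas1 (−3.48) and Galnt12 (−1.66) falling and Foxa3 (1.34) rising, with 2 not passing and the same 1 and 2 adjusted over the list alone. The median was −0.82 (camera adjusted p = 0.0241, and adjusted p = 0.279 with an estimated correlation). Without a filter the median was 0 with camera adjusted p = 0.393, and on scaling without Rn18s it was −0.64 with camera adjusted p = 0.0839. P53 targets had 1 higher, Gdf15 (1.98), and 5 lower, among them Pmaip1 (−1.39), Trp53inp1 (−1.68) and Psrc1 (−1.41), with 17 not passing and 1 and 5 adjusted over the list alone. Their median was −0.36 (camera adjusted p = 0.00992, and adjusted p = 0.472 with an estimated correlation). Without library 1 of control that list had a camera adjusted p = 0.0712. Hypoxia and glycolysis had 1 higher, 4 lower and 18 not passing, with 1 and 6 adjusted over the list alone. The median was −0.39 (camera adjusted p = 0.0157, and adjusted p = 0.724 with an estimated correlation). Without library 3 of the knockout its camera adjusted p = 0.148.

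The remaining lists had no call by camera, though single genes changed. The IFNg response core had 2 higher, 4 lower and 27 not passing, with 4 and 5 adjusted over the list alone (adjusted p = 0.814); Parp14 (−2.20) and Socs3 (−1.88) fell, and its median of 0.11 had the opposite sign to the test. The type I interferon-associated list had 3 higher, 3 lower and 24 not passing, the same adjusted over the list alone (adjusted p = 0.814), with Usp18 (1.86) and Bst2 (1.56) up and Oas1a (−2.69) down. MHC class I had 3 higher, 4 lower and 15 not passing (3 and 6 adjusted over the list alone; adjusted p = 0.531), with B2m up 1.63 ± 0.25 and Tap2 down (−1.35). Its median was 0.09 and its mean −0.02. Of death genes, pro-apoptotic Bok rose (1.43) and Pmaip1 fell in a list of 2 higher, 3 lower and 24 not passing (2 and 3 adjusted over the list alone; adjusted p = 0.512). Anti-apoptotic genes had 1 higher, 1 lower and 13 not passing, the same adjusted over the list alone (adjusted p = 0.531). The pore former Gsdmc2 (−3.50, but adjusted p = 0.0906 without a filter) and the necroptosis effector Mlkl (−0.95) fell in a list of 1 higher, 3 lower and 17 not passing, with 1 and 5 adjusted over the list alone (adjusted p = 0.0554). Of Wnt targets, Prox1 (2.96) and Wif1 (2.75) rose and Dkk2 fell (−1.88), with 6 higher, 2 lower and 12 not passing (7 and 4 adjusted over the list alone; adjusted p = 0.531). Among KRAS-ERK outputs Etv5 (3.05), Areg (3.04), Spry4 (1.51) and Spry1 (1.42) rose, with 6 higher, 0 lower and 19 not passing (7 and 0 adjusted over the list alone; adjusted p = 0.0554). Colonocyte genes split, Krt20 (2.33) and Cdhr2 (2.56) up and Car1 (−3.63) down, with 5 higher, 4 lower and 5 not passing (6 and 4 adjusted over the list alone; adjusted p = 0.46). Among genes with a mean of at least 5 CPM the colonocyte median was −0.94, lower as a set (adjusted p = 0.0181), against 0.76 in the full list.

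Of 32 proliferation genes, 0 passed by limma, by edgeR or by DESeq2, nor adjusted over the list alone, and 3 were higher at an unadjusted p under 0.05; Aurka was nearest (0.82, adjusted p = 0.0511; list adjusted p = 0.87). Intestinal stem cell genes had 2 higher, 1 lower and 15 not passing, with 2 and 5 adjusted over the list alone (adjusted p = 0.425). The JAK-STAT components had 2 higher, 2 lower (4 after rescaling) and 14 not passing, with 2 and 3 adjusted over the list alone (adjusted p = 0.449). BET proteins and P-TEFb had 1 higher, 0 lower and 16 not passing, with 0 and 0 adjusted over the list alone (adjusted p = 0.531). Of the NF-kB list, Cxcl1 (2.26) and Nfkbia (1.01) rose, with 4 higher, 0 lower and 18 not passing, the same adjusted over the list alone (adjusted p = 0.531). In cholesterol biosynthesis Pcsk9 alone rose (3.00), also adjusted over the list alone (adjusted p = 0.0815). Oxidative phosphorylation had 5 higher (2 after rescaling), 0 lower and 22 not passing, with 6 and 0 adjusted over the list alone (adjusted p = 0.0665). Epithelial junction genes had Cldn7 up (1.70) and Lama3 down (−1.91), with 20 not passing and the same adjusted over the list alone (adjusted p = 0.994). Of lists too small to test, Cpe was the only enteroendocrine gene measured (0.37, adjusted p = 0.314), 1 of 3 tuft genes was higher, Vim (0.27, adjusted p = 0.752) and the other stromal gene did not pass, and of 2 immune genes S100a8 was higher (2.87, adjusted p = 0.000594, but 0.0869 by edgeR and 0.264 by DESeq2).

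**Figure D1:**
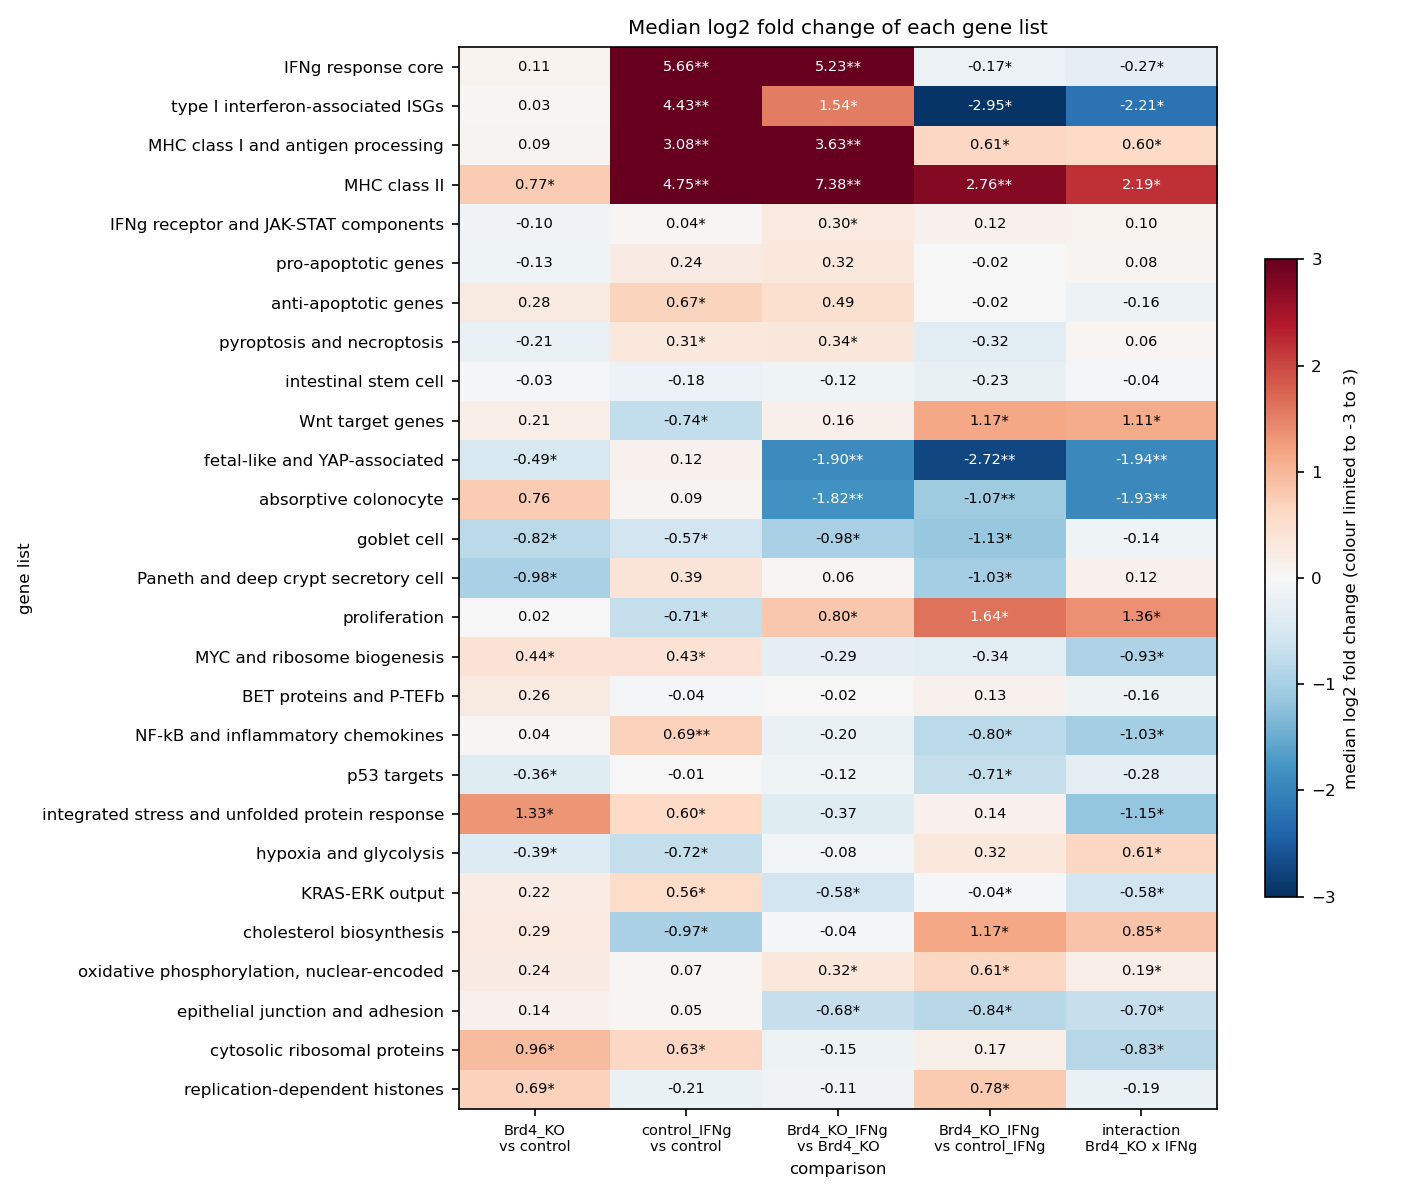
Median log2 fold change of the measured genes in each of 27 tested lists (down the side) for 5 comparisons (across), on the log2(CPM + 1) scale with colour limited to −3 to 3. A star marks a camera adjusted p under 0.05 at the preset correlation, and 2 stars one that also held with an estimated correlation.

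Control organoids with IFNg against those without ask what IFNg does where Brd4 is intact. The STAT1 program rose steeply. Stat1 (1:52158599-52201024) went from 5.62 ± 1.1 CPM (SD, n = 4) to 155 ± 37.4 CPM (SD, n = 3), Irf1 from 8.6 ± 1.63 to 205 ± 31.4 CPM, and the class II invariant chain Cd74 from 0.208 to 732 CPM. The chemokines Cxcl9, Cxcl10 and Cxcl11, the tryptophan-degrading enzyme Ido1, the antiviral genes Rsad2 and Ifit3 and the checkpoint ligand gene Cd274 appeared from next to nothing. Of Wnt targets 9 of 20 fell, of cholesterol synthesis genes 15 of 25 and of proliferation genes 4 of 32 (adjusted p = 0.102, adjusted p = 0.118 and adjusted p = 0.449 with an estimated correlation). Proliferation genes such as Plk1 were not lower in library 2 of control with IFNg.

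By limma 767 genes were higher and 861 lower, 585 and 606 of them over 2-fold; the lower count was 469 without library 1 of control with IFNg and 572 without its library 3. Stat1 rose by 4.54 ± 0.25 (adjusted p = 9.32e-11), Irf1 by 4.43 ± 0.28 (adjusted p = 6.61e-10), Cxcl10 by 6.79 ± 0.34 (adjusted p = 2.56e-11), Cd274 by 4.21 ± 0.43 (adjusted p = 8.66e-07), Cd74 by 9.26 ± 0.20 (adjusted p = 1.5e-16), and the GTPase genes Gbp2 by 8.51 ± 0.26, Igtp by 8.09 ± 0.26 and Gbp4 by 7.80. Genes at 0 in every untreated control library rose by at least 15500-fold (Iigp1), 8360-fold (Tgtp1), 8040-fold (Tgtp2), 5920-fold (Ido1), 4160-fold (Cxcl11), 3520-fold (Cxcl9), 3250-fold (Zbp1), 2250-fold (Rsad2) and 1760-fold (Ifit3). Tgtp1 and Tgtp2 are near copies, as are several Gbp and Ifit genes, so their reads may be shared. Largest falls were in Dapl1 (−5.96 ± 0.58), Apoc4 (−5.47 ± 0.31), Gstm7 (−4.82), Lypd2 (−4.08), Pgm2l1 (−3.92), Rnf186 (−3.69), Gstm1 (−3.47) and the Wnt effector Lef1 (−3.41). Myc rose from 77.2 ± 24.8 to 139 ± 36.1 CPM (0.86, adjusted p = 0.0144; SD, n = 4 and n = 3), but with adjusted p = 0.106 without library 1 of control with IFNg (0.66), and 0.0515 and 0.0524 without library 2 and library 3 of control (0.79 and 0.78). Ifngr1 (0.59, adjusted p = 0.366), Ifngr2 (−0.21, adjusted p = 0.509), Jak1 (−0.29, adjusted p = 0.427), Jak2 (0.06, adjusted p = 0.949), Casp8 (0.32, adjusted p = 0.452) and Brd4 (0.40, adjusted p = 0.244) did not pass.

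Of the IFNg response core, 32 of 33 were higher, 0 lower and 1 not passing, the same adjusted over the list alone. The median was 5.66, or 7.8 with the 15 members at 0 in control set at their lower bound (camera adjusted p = 4.28e-80, and 1.01e-07 with an estimated correlation). Type I interferon-associated genes, which include Xaf1 (5.30), Usp18 (3.91) and Stat2 (2.58), were higher in 29, lower in 0 and not passing in 1, with 30 and 0 adjusted over the list alone. The median was 4.43, or 5.08 with 9 members at their bound (camera adjusted p = 3.81e-50, and 0.00336 with an estimated correlation). For MHC class I, B2m rose by 6.50 ± 0.25, Psmb9 by 6.22 and H2-Q7 by 6.06, with 20 higher, 0 lower and 2 not passing, and 21 and 0 adjusted over the list alone. Its median was 3.08 (camera adjusted p = 1.64e-40, and 3.11e-05 with an estimated correlation). MHC class II had H2-Eb1 up 6.94 and H2-Ab1 up 6.14, with 8 higher, 0 lower and 3 not passing, the same adjusted over the list alone. The median was 4.75, or 5.38 with 3 members at their bound (camera adjusted p = 1.65e-22, and 0.00204 with an estimated correlation). In the NF-kB list Ccl5 (5.93), Nos2 (2.95) and Nfkbia (1.27) rose, with 6 higher, 0 lower and 16 not passing, and 7 and 0 adjusted over the list alone. The median was 0.69 (camera adjusted p = 6.12e-06, and 0.0448 with an estimated correlation).

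Death genes moved on both sides. Pyroptosis and necroptosis had Casp4 (2.57) and Casp12 (2.26) up, with 7 higher, 2 lower and 12 not passing, and 7 and 3 adjusted over the list alone. Its median was 0.31 (camera adjusted p = 0.0117, and adjusted p = 0.118 with an estimated correlation). Anti-apoptotic Tnfaip8 (1.36) and Mcl1 (1.20) rose, with 4 higher, 0 lower and 11 not passing, the same adjusted over the list alone. The median was 0.67 (camera adjusted p = 0.00398, and adjusted p = 0.101 with an estimated correlation). Pro-apoptotic genes, with Xaf1, Tnfsf10 (3.54) and Tnfrsf1a (1.71) up, had 6 higher, 6 lower and 17 not passing, and 8 and 6 adjusted over the list alone (adjusted p = 0.139). JAK-STAT components, the suppressor Socs1 (4.91) among them, had 5 higher, 0 lower and 13 not passing, the same adjusted over the list alone. Their median was 0.04 (camera adjusted p = 0.00394, and adjusted p = 0.118 with an estimated correlation).

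Of Wnt targets, with Nkd1 (−2.44), Wif1 (−2.17) and Lef1 down, 2 were higher, 9 lower and 9 not passing, with 2 and 10 adjusted over the list alone. The median was −0.74 (camera adjusted p = 9.47e-05, and adjusted p = 0.102 with an estimated correlation). Cholesterol biosynthesis fell, with Acat2 (−2.14 ± 0.32), Hmgcs1 (−2.08), Idi1 (−1.70) and Sqle (−1.45) the most: 0 were higher, 15 lower and 10 not passing, with 0 and 19 adjusted over the list alone. Its median was −0.97 (camera adjusted p = 2.78e-11, and adjusted p = 0.118 with an estimated correlation). Proliferation genes had 0 higher, 4 lower and 28 not passing, with 0 and 7 adjusted over the list alone (camera adjusted p = 0.000204, and adjusted p = 0.449 with an estimated correlation). Library 2 of control with IFNg was not lower: Plk1 was at 3.56, 32.1 and 7.78 CPM in libraries 1 to 3, against 24.3 to 31.8 CPM in control. The list median of −0.71 was −1.2 without library 2 and −0.34 without library 1. Hypoxia and glycolysis, with Bnip3 (−2.39), Bnip3l (−1.70) and P4ha2 (−1.60) down and Hk2 up 1.74, had 1 higher, 7 lower and 15 not passing, and 1 and 11 adjusted over the list alone. The median was −0.72 (camera adjusted p = 0.000146, and adjusted p = 0.36 with an estimated correlation). Ribosomal protein genes, with Rpl13 (2.10), Rps2 (1.85) and Rplp1 (1.26), had 19 higher, 0 lower and 12 not passing, and 25 and 0 adjusted over the list alone. Their median was 0.63 (camera adjusted p = 1.37e-15, and adjusted p = 0.118 with an estimated correlation). The integrated stress list, with Atf4 up 1.37, had 5 higher, 0 lower and 18 not passing, and 9 and 1 adjusted over the list alone. The median was 0.60 (camera adjusted p = 0.000233, and adjusted p = 0.249 with an estimated correlation). Genes such as Chac1 (67.1, 8.94 and 69.1 CPM in libraries 1 to 3, against 5.49 to 16.9 CPM in control) rose in 2 of the 3 libraries. KRAS-ERK outputs, with Areg (3.02) and Dusp6 (1.45) up, had 7 higher, 2 lower and 16 not passing, and 10 and 3 adjusted over the list alone. Their median was 0.56 (camera adjusted p = 0.0347, and adjusted p = 0.34 with an estimated correlation). The camera adjusted p = 0.181 and 0.113 without library 1 and library 3 of control with IFNg, and 0.0512 without library 3 of control. Goblet (median −0.57, Bcas1 at −3.38) and MYC and ribosome biogenesis (median 0.43) had camera adjusted p = 0.0117 and 0.0042, with adjusted p = 0.118 and adjusted p = 0.566 with an estimated correlation; goblet was at 0.0675 without library 3 of control with IFNg and MYC at 0.0768 without library 2. Intestinal stem cell, with 0 higher and 3 lower, fetal-like, with 3 and 3, and colonocyte, with 2 and 3, had no call by camera (adjusted p = 0.135, 0.743 and 0.743); adjusted over the list alone they had 0 and 3, 3 and 3, and 4 and 3.

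**Figure D2:**
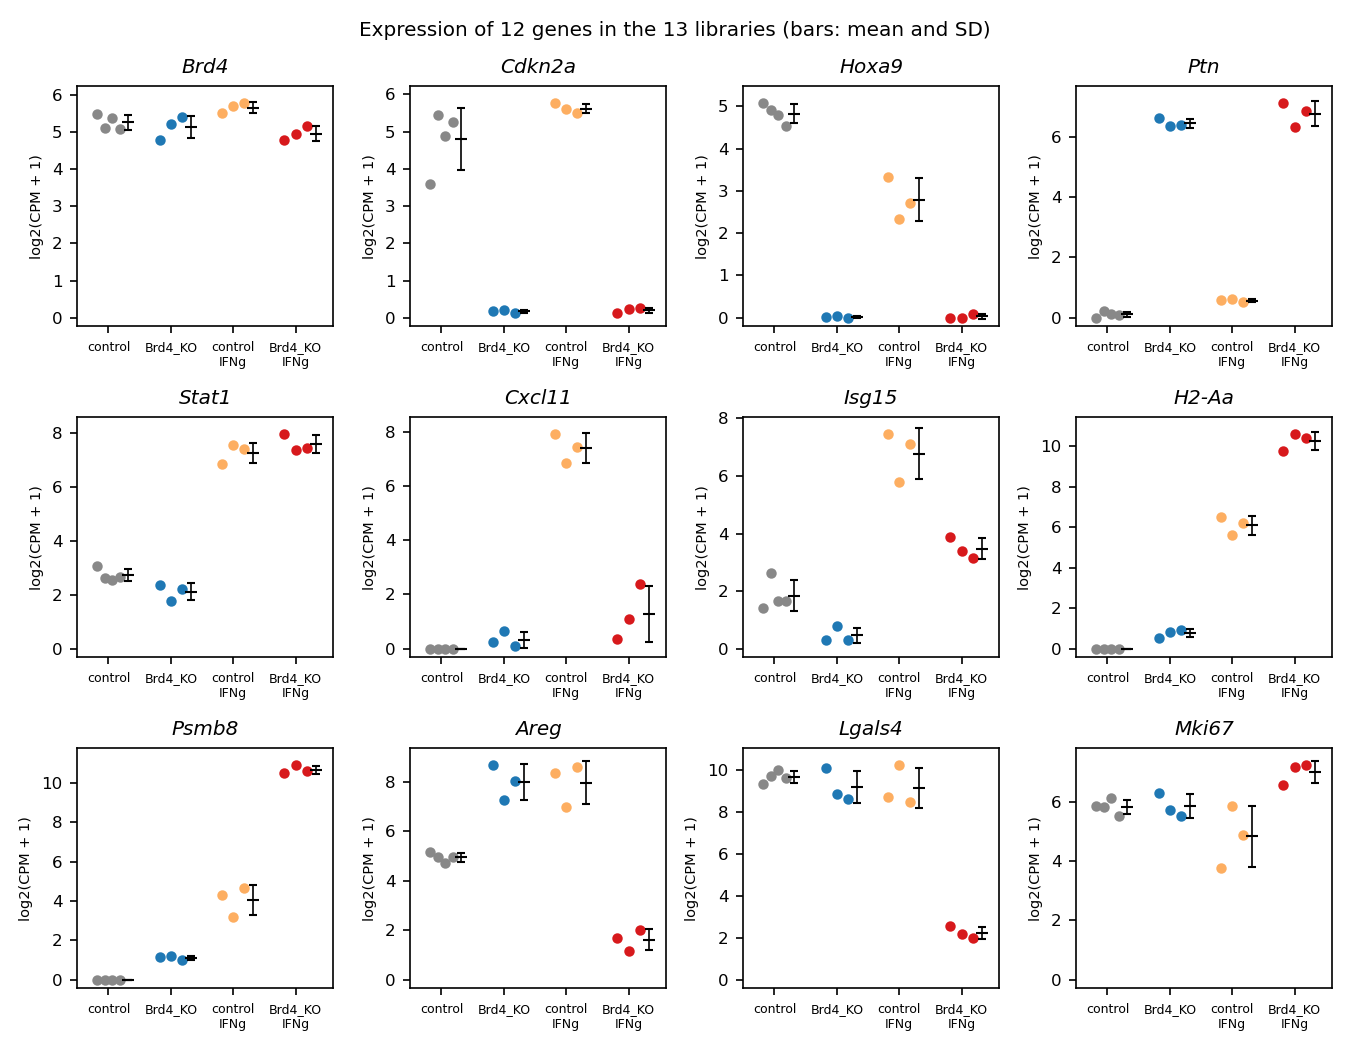
Expression of 12 genes in each of the 13 libraries as log2(CPM + 1), by group; points are libraries and bars give mean and SD (control n = 4, other groups n = 3).

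Knockout organoids with IFNg against those without ask which part of the IFNg response goes on in organoids labelled knockout. Core STAT1 genes rose: Stat1 went from 3.39 ± 0.915 to 192 ± 46 CPM (SD, n = 3 and n = 3), Irf1 from 4.08 ± 1.9 to 144 ± 40.8 CPM and B2m from 87.6 to 3725 CPM. MHC class II and the immunoproteasome gene Psmb8 rose to high levels, with H2-Aa at 1260 ± 359 CPM and Psmb8 at 1660 ± 250 CPM (SD, n = 3 each). Type I interferon-associated genes rose in 17 of 30 (adjusted p = 0.101 with an estimated correlation), and the chemokine gene Cxcl10 rose to 6.34 ± 2.42 CPM (SD, n = 3). Fetal-like genes fell in 13 of 19 and colonocyte genes in 9 of 14. Among single epithelial genes, Lgals4 fell from 639 ± 373 to 3.78 ± 0.97 CPM, Areg from 275 ± 129 to 2.17 ± 0.904 CPM and Krt19 from 602 ± 32.2 to 50 ± 5.79 CPM (SD, n = 3 and n = 3).

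By limma 975 genes were higher and 1008 lower, 757 and 878 over 2-fold; the higher count was 629 without library 2 of the knockout with IFNg. Stat1 rose by 5.45 ± 0.27 (adjusted p = 1.44e-11), Irf1 by 4.87 ± 0.29 (adjusted p = 3.84e-10), Psmb8 by 9.57 ± 0.33 (adjusted p = 7.68e-14), H2-Aa by 9.48 ± 0.29, H2-Eb1 by 9.13 ± 0.25, H2-Ab1 by 8.63, Cd74 by 8.44, Igtp by 8.65, Tgtp1 by 8.41 and Iigp1 by 8.16. Smaller rises were those of Cd274 (2.44 ± 0.46, adjusted p = 0.000844), Cxcl10 (2.47 ± 0.36, adjusted p = 7.78e-05) and Ido1 (3.26 ± 0.45, adjusted p = 3.36e-05). The largest falls were in Lgals4 (−6.93 ± 0.38, adjusted p = 1.01e-10), Areg (−6.37 ± 0.38, adjusted p = 2.69e-10), Prr9 (−6.68), Calml4 (−5.66), Fabp4 (−5.62), Krtap3-3 (−6.93), Krtap3-1 (−6.60) and Krtap3-2 (−5.56). Myc fell (−0.95, adjusted p = 0.00948) and so did Ifngr2 (−1.09, adjusted p = 0.000554). Ifngr1 fell with adjusted p = 0.0457 (−1.25) and Jak2 rose with adjusted p = 0.0164 (1.32), and each call was lost under other settings. Ifngr1 had adjusted p = 0.0518 to 0.184 in 8 of them beside the leaving out of libraries, the replicate block (0.0573) and edgeR (0.0801) included. Jak2 had adjusted p = 0.0615 without a filter, 0.0765 without library 2 of the knockout with IFNg (1.19), and 0.0626 and 0.0636 without library 2 and library 3 of the knockout (1.25 each). Ifngr1, at −0.92 to −1.38, had adjusted p = 0.0722 to 0.182 without library 1 or 3 of the knockout or 1 or 2 of the knockout with IFNg, and 0.0543 to 0.0587 without library 2, 3 or 4 of control or 3 of control with IFNg. Jak1 (0.10, adjusted p = 0.841), Casp8 (0.76, adjusted p = 0.059) and Brd4 (−0.17, adjusted p = 0.677) did not pass.

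Of the IFNg response core, 31 were higher, 0 lower and 2 not passing, with 32 and 0 adjusted over the list alone. The median was 5.23 (camera adjusted p = 4.64e-61, and 3.41e-07 with an estimated correlation). MHC class I, with Psmb9 up 8.01 and Tap1 up 6.35, had 21 higher, 0 lower and 1 not passing, the same adjusted over the list alone. Its median was 3.63 (camera adjusted p = 2.47e-39, and 3.47e-05 with an estimated correlation). MHC class II had 10 higher, 0 lower and 1 not passing, the same adjusted over the list alone. The median was 7.38, or 7.53 with 1 member at its bound (camera adjusted p = 3.14e-27, and 0.000962 with an estimated correlation). Type I interferon-associated genes, with Zbp1 (5.99), Ifi44 (3.82), Usp18 (3.63) and Ifit2 (3.29) the most, had 17 higher, 0 lower and 13 not passing, and 21 and 0 adjusted over the list alone. Their median was 1.54 (camera adjusted p = 2.18e-13, and adjusted p = 0.101 with an estimated correlation). JAK-STAT components, with Socs1 up 4.72, had 8 higher, 2 lower and 8 not passing, the same adjusted over the list alone. The median was 0.30 (camera adjusted p = 0.00159, and adjusted p = 0.103 with an estimated correlation).

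Fetal-like and YAP-associated genes fell, with Ccn2 (−4.96 ± 0.40), Il1rn (−4.95 ± 0.38), Anxa8 (−3.23) and Cd55 (−3.18): 0 were higher, 13 lower and 6 not passing, the same adjusted over the list alone. Their median was −1.90 (camera adjusted p = 1.19e-12, and 0.00424 with an estimated correlation). Colonocyte genes fell, with Car1 (−4.47), Cdhr5 (−3.69), Cdhr2 (−3.21) and Krt20 (−2.32): 0 were higher, 9 lower and 5 not passing, with 0 and 14 adjusted over the list alone. The median was −1.82, or −1.94 with 1 member at its bound (camera adjusted p = 3.21e-12, and 0.00217 with an estimated correlation). Junction and keratin genes fell, with Krt19 (−3.57 ± 0.18, adjusted p = 1.82e-11), Cldn4 (−2.05), Krt8 (−1.69) and Dsp (−1.62): 0 were higher, 9 lower and 13 not passing, with 0 and 14 adjusted over the list alone. Their median was −0.68 (camera adjusted p = 3.13e-06, and adjusted p = 0.103 with an estimated correlation). Goblet genes, with Foxa3 (−3.36) and Agr2 (−3.09), had 0 higher, 2 lower and 3 not passing, and 0 and 3 adjusted over the list alone. The median was −0.98, or −3.36 with 2 members at their bound (camera adjusted p = 0.000667, and adjusted p = 0.0535 with an estimated correlation). KRAS-ERK outputs fell, with Ereg (−3.85) and Fosl1 (−2.95) beside Areg: 3 were higher, 10 lower and 12 not passing, the same adjusted over the list alone. Their median was −0.58 (camera adjusted p = 0.000667, and adjusted p = 0.132 with an estimated correlation). Proliferation moved up as a set, with 4 higher, 0 lower and 28 not passing, the same adjusted over the list alone. The median was 0.80 (camera adjusted p = 2.39e-05, and adjusted p = 0.5 with an estimated correlation). Oxidative phosphorylation did so too, with a median of 0.32 (camera adjusted p = 0.000867, and adjusted p = 0.547 with an estimated correlation). Pyroptosis and necroptosis, with Casp12 (3.18) and Mlkl (3.03 ± 0.24) up, had 6 higher, 2 lower and 13 not passing, and 6 and 3 adjusted over the list alone. The median was 0.34 (camera adjusted p = 0.0398, and adjusted p = 0.162 with an estimated correlation). The camera adjusted p = 0.0533 to 0.0793 without library 1 or 3 of the knockout with IFNg, 1 or 2 of the knockout, or 2 of control with IFNg. Pro-apoptotic Xaf1 (2.80) and Tnfsf10 (2.07) rose in a list of 7 higher, 3 lower and 19 not passing, with 9 and 5 adjusted over the list alone (adjusted p = 0.134). Of 31 ribosomal proteins, 0 passed by limma, nor adjusted over the list alone, with Rplp0 nearest (−0.49, adjusted p = 0.0777; list adjusted p = 0.226); 3 were lower at an unadjusted p under 0.05, and 1 was lower by edgeR and 1 by DESeq2.

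The knockout against control, both with IFNg, asks which genes differ between treated organoids given the Brd4 guide and those given the non-targeting guide. Stat1 and Irf1 did not pass, but several antiviral and chemokine genes were low in the knockout. Cxcl11 was at 1.88 ± 2.05 CPM against 175 ± 63 CPM in control, Rsad2 at 1.98 ± 2.33 against 94.4 ± 26.7, Ido1 at 15.5 ± 14.3 against 249 ± 84.7 and Cd274 at 8.14 ± 4.22 against 30.6 ± 12.2 (SD, n = 3 each). MHC class II and Psmb8 were far higher in the knockout. Of 20 Wnt targets 11 were higher, such as Nkd1 (343 ± 96.7 against 9.41 ± 5.34 CPM), and 3 lower (adjusted p = 0.111 with an estimated correlation). Of 32 proliferation genes 21 were higher, such as Mki67 (130 ± 30.3 against 32.6 ± 22.1 CPM; SD, n = 3 each), with adjusted p = 0.209 with an estimated correlation. Fetal-like genes were lower in 16 of 19 and colonocyte genes in 9 of 14, and Plac8 was at 6.98 ± 5.98 against 1280 ± 395 CPM (SD, n = 3 each).

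By limma 1971 genes were higher and 1224 lower, 1388 and 1048 over 2-fold. Median-of-ratios rescaling moved the median log2 fold change by −0.139 and gave 1485 higher and 1562 lower, with 2709 shared; changes here are relative to that shift. The largest rises were in the protease gene Gzma (6.84 ± 0.35), Psmb8 (6.63 ± 0.33), Adgrg2 (6.21), Ptn (6.20 ± 0.29), Lypd2 (6.17), the stem cell factor Sox2 (5.98 ± 0.35), Fermt2 (5.95) and Faim2 (5.73). The largest falls were in Plac8 (−7.57 ± 0.40, adjusted p = 1.5e-10), Ly6g (−6.96), Lgals4 (−6.90), Ms4a8a (−6.84), Car1 (−6.78), Areg (−6.35), Samd5 (−6.14) and Cxcl11 (−6.11 ± 0.44, adjusted p = 7.86e-09). Cxcl10 (−4.10 ± 0.36, adjusted p = 1.17e-07), Ido1 (−4.20 ± 0.45, adjusted p = 1.22e-06), Cd274 (−1.84 ± 0.46, adjusted p = 0.00587) and Myc (−1.18 ± 0.24, adjusted p = 0.00116) were lower. With library 3 of control with IFNg and library 1 of the knockout with IFNg left out together, Cd274 was at −1.12 with adjusted p = 0.101. Stat1 (0.31, adjusted p = 0.436), Irf1 (−0.54, adjusted p = 0.201), Ifngr1 (−1.03, adjusted p = 0.0761), Ifngr2 (−0.42, adjusted p = 0.125), Jak1 (0.10, adjusted p = 0.815), Jak2 (0.28, adjusted p = 0.628) and Casp8 (0.15, adjusted p = 0.743) did not pass.

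Type I interferon-associated genes were lower, with Rsad2 (−5.23 ± 0.45), Ifit3 (−4.83) and Oas3 (−4.43) the most: 1 was higher (Usp18, 1.58, adjusted p = 0.0932 by edgeR), 22 lower and 7 not passing, with 1 and 23 adjusted over the list alone. Their median was −2.95 (camera adjusted p = 1.66e-16, and adjusted p = 0.0664 with an estimated correlation). MHC class II was higher, with H2-Aa (4.15 ± 0.29), H2-Ab1 (3.35), H2-Eb1 (3.17) and H2-DMa (2.87): 9 were higher, 0 lower and 2 not passing, the same adjusted over the list alone. The median was 2.76 (camera adjusted p = 7.57e-10, and 0.0352 with an estimated correlation). MHC class I, with Psmb8 and Tap2 (1.66) up and H2-Q6 (−3.46) down, had 9 higher, 1 lower and 12 not passing, the same adjusted over the list alone. Its median was 0.61 (camera adjusted p = 0.00653, and adjusted p = 0.122 with an estimated correlation). The IFNg response core had 3 higher, 9 lower and 21 not passing, with 5 and 10 adjusted over the list alone. The median was −0.17 (camera adjusted p = 0.00653, and adjusted p = 0.0534 with an estimated correlation). The camera adjusted p = 0.052 without library 1 of the knockout with IFNg. NF-kB genes, with Ccl5 (−4.70), Tnfaip2 (−4.33) and Icam1 (−2.42), had 1 higher, 9 lower and 12 not passing, and 1 and 10 adjusted over the list alone (camera adjusted p = 0.000317, and adjusted p = 0.0844 with an estimated correlation).

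Of death genes, Casp4 (−2.32) and the necroptosis kinase gene Ripk3 (−1.52 ± 0.25, adjusted p = 0.000194) were lower in a list of 1 higher, 4 lower and 16 not passing, the same adjusted over the list alone (adjusted p = 0.066). Pro-apoptotic Xaf1 (−2.46) was lower in a list of 2 higher, 4 lower and 23 not passing, the same adjusted over the list alone. Anti-apoptotic Birc5 (1.73) and Bag1 (1.14) were higher and Tnfaip8 (−2.31) lower, with 3 higher, 2 lower and 10 not passing, and 4 and 2 adjusted over the list alone. P53 targets, with Btg2 (−2.44) and Zmat3 (−1.63), had 0 higher, 9 lower (14 after rescaling) and 14 not passing, and 0 and 11 adjusted over the list alone. Their median was −0.71 (camera adjusted p = 0.000105, and adjusted p = 0.15 with an estimated correlation).

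Fetal-like genes were lower, with Anxa8 (−4.79), Cd55 (−4.51 ± 0.22), Il1rn (−4.41) and Ly6d (−4.38): 0 were higher, 16 lower and 3 not passing, with 0 and 18 adjusted over the list alone. The median was −2.72 (camera adjusted p = 2.61e-20, and 0.00309 with an estimated correlation). Colonocyte genes, with Ceacam1 (−3.79) and Cdhr5 (−3.01) beside Car1, had 0 higher, 9 lower and 5 not passing, the same adjusted over the list alone. Their median was −1.07 (camera adjusted p = 2.32e-06, and 0.0352 with an estimated correlation). Junction genes, with Cldn1 (−3.93), Krt19 (−3.58 ± 0.18) and Krt8 (−1.90), had 1 higher, 14 lower and 7 not passing, and 1 and 15 adjusted over the list alone. The median was −0.84 (camera adjusted p = 8.37e-08, and adjusted p = 0.0664 with an estimated correlation). Wnt targets Nkd1 (5.16 ± 0.35), Wif1 (4.90 ± 0.29), Prox1 (4.60) and Apcdd1 (3.56) were higher in a list of 11 higher, 3 lower and 6 not passing, with 12 and 4 adjusted over the list alone. Their median was 1.17 (camera adjusted p = 0.0003, and adjusted p = 0.111 with an estimated correlation). Proliferation genes, with Ccnb2 (2.72 ± 0.39), Ccnb1 (2.59) and Plk1 (2.38), had 21 higher, 0 lower and 11 not passing, and 28 and 0 adjusted over the list alone. The median was 1.64 (camera adjusted p = 2.84e-09, and adjusted p = 0.209 with an estimated correlation). Cholesterol genes, with Pcsk9 (3.12), Fdps (1.90) and Pmvk (1.86), had 19 higher, 0 lower and 6 not passing, and 21 and 0 adjusted over the list alone. Their median was 1.17 (camera adjusted p = 8.23e-09, and adjusted p = 0.163 with an estimated correlation). Oxidative phosphorylation, with Ndufb8 up 1.28, had 17 higher, 0 lower and 10 not passing, and 18 and 0 adjusted over the list alone. The median was 0.61 (camera adjusted p = 2.96e-05, and adjusted p = 0.323 with an estimated correlation). After rescaling 6 were higher. Histone genes, with H1f0 (2.44), itself not replication-dependent, had 6 higher, 0 lower and 14 not passing, the same adjusted over the list alone. Their median was 0.78 (camera adjusted p = 0.00132, and adjusted p = 0.323 with an estimated correlation).

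Goblet (median −1.13, or −3.01 with 2 members at their bound; Agr2 at −3.01) and Paneth (median −1.03, or −1.23 with 1 member at its bound; Itln1 at −1.85) had camera adjusted p = 0.000327 and 0.00368, and adjusted p = 0.0534 and adjusted p = 0.122 with an estimated correlation. KRAS-ERK outputs split, Etv5 (3.61) up and Ereg (−5.24) and Fos (−3.88) down, with 7 higher (4 after rescaling), 10 lower and 8 not passing, and 7 and 11 adjusted over the list alone. The median was −0.04 and the mean −0.85 (camera adjusted p = 0.0115, and adjusted p = 0.22 with an estimated correlation). Without library 1 of the knockout with IFNg its camera adjusted p = 0.0654. The secretory regulator Xbp1 (3.06 ± 0.24, adjusted p = 3.04e-08) and the chaperone gene Hsp90b1 (1.52) were higher in a stress list of 6 higher, 1 lower and 16 not passing, with 7 and 1 adjusted over the list alone, which had no call by camera.

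**Figure D3:**
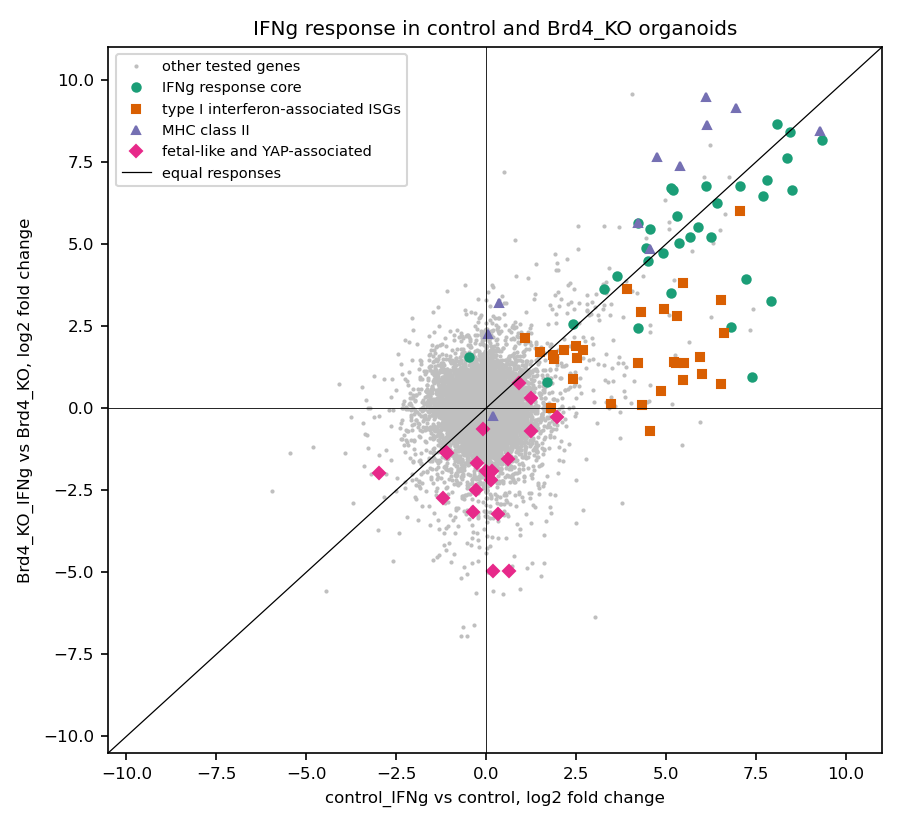
The IFNg response of each tested gene in control organoids (across) and in knockout organoids (up), as log2 fold change on the log2(CPM + 1) scale; members of 4 lists are coloured and the diagonal marks equal responses. No library is shared between the 2 axes.

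The interaction asks which IFNg responses differ between knockout and control. Of type I interferon-associated genes 19 of 30 responded less in the knockout, and of NF-kB and chemokine genes 7 of 22 (adjusted p = 0.103 each with an estimated correlation). Cxcl10 reached 6.34 CPM there and 125 CPM in control, and Cxcl11, Ido1, Rsad2 and Ifit3 followed the same course. Areg went opposite ways, from 30.2 ± 3.96 (SD, n = 4) to 279 ± 137 CPM (SD, n = 3) in control and from 275 to 2.17 CPM in the knockout, and Myc likewise rose from 77.2 to 139 CPM in control and fell from 116 to 60 CPM in the knockout. Of 20 Wnt targets 7 had a more positive response in the knockout and 2 a more negative one (adjusted p = 0.103 with an estimated correlation). Among them Nkd1 went from 50.7 ± 11.7 to 9.41 CPM in control and from 108 ± 30.4 to 343 CPM in the knockout (SD, n = 4 and n = 3 for the untreated groups). Stat1 and Irf1 responses did not differ by this test.

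By limma 1006 responses were more positive and 968 more negative in the knockout, 942 and 933 by over 2-fold. The most negative were Areg (−9.39 ± 0.51, adjusted p = 2.93e-09), the protease inhibitor Slpi (−6.67 ± 1.02), Sprr2h (−6.65), Prss2 (−6.57), Ly6g (−6.47) and Cxcl11 (−6.44 ± 0.60), with Cxcl10 at −4.32 ± 0.50 (adjusted p = 1.32e-05), Ido1 at −4.64 ± 0.61 (adjusted p = 5.3e-05) and Myc at −1.81 ± 0.33 (adjusted p = 0.00103). Most positive were Gzma (6.69 ± 0.47, adjusted p = 5.24e-08), Psmb8 (5.53 ± 0.45), Lypd2 (4.82), Def6 (4.80), Zfp503 (4.42) and Hacd4 (4.35). By edgeR, Gzma was at 3.79 with adjusted p = 0.94 and Psmb8 at −1.71 with adjusted p = 0.548, since both were near or at 0 in untreated libraries and a ratio from there is unbounded; their levels with IFNg do not share that limit. Ido1, Cxcl11, Rsad2 and Ifit3 were, like Gzma and Psmb8, at 0 in untreated control, so the size of these 6 interaction values rests on the added 1 CPM. Ifngr1 (−1.84, adjusted p = 0.0322) and Ifngr2 (−0.88, adjusted p = 0.0309) passed with all libraries but not on leaving out some, where Ifngr1 was at −1.51 to −1.80 and Ifngr2 at −0.77 to −0.90. For Ifngr1 the adjusted p was 0.0575 to 0.0969 without library 1 or 3 of control with IFNg, 1 or 3 of the knockout, 1 of control, or 1 of the knockout with IFNg. For Ifngr2 it was 0.0547 to 0.0911 without library 2 of the knockout with IFNg, 3 of control with IFNg, any 1 of the knockout, or 1 or 3 of control. Stat1 (0.91, adjusted p = 0.101), Irf1 (0.44, adjusted p = 0.512), Cd274 (−1.77, adjusted p = 0.0625), Jak1 (0.39, adjusted p = 0.448), Jak2 (1.27, adjusted p = 0.0926), Casp8 (0.44, adjusted p = 0.463) and Brd4 (−0.57, adjusted p = 0.229) did not pass.

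Type I interferon-associated genes had 0 more positive, 19 more negative and 11 not passing, with 0 and 21 adjusted over the list alone, Rsad2 (−5.80 ± 0.61), Oasl1 (−5.24) and Ifit3 (−4.96) the most. Their median was −2.21, or −1.92 without 9 members at 0 in a group (camera adjusted p = 5.31e-14, and adjusted p = 0.103 with an estimated correlation). The IFNg response core had 3 more positive, 7 more negative and 23 not passing, with 5 and 10 adjusted over the list alone. Its median was −0.27, but 0.37 without the 15 members at 0 in a group (camera adjusted p = 0.0319, and adjusted p = 0.103 with an estimated correlation). The camera adjusted p = 0.148 without library 1 of the knockout with IFNg, and 0.0551 and 0.0603 without library 1 and library 3 of control with IFNg. MHC class I, with Tap2 (3.01) and H2-T22 (2.30), had 6 more positive, 1 more negative and 15 not passing, and 7 and 2 adjusted over the list alone. The median was 0.60 (camera adjusted p = 0.00328, and adjusted p = 0.103 with an estimated correlation). MHC class II had 8 more positive, 0 more negative and 3 not passing, with 8 and 1 adjusted over the list alone. Its median was 2.19 (camera adjusted p = 5.41e-06, and adjusted p = 0.103 with an estimated correlation). By edgeR, 1 class II response was more positive and 2 more negative (median −0.79), so this interaction rests on the scale. The treated knockout's higher level does not: 9 of 11 were higher by edgeR too (median 2.7). NF-kB genes, with Ccl5 (−6.37), Tnfaip2 (−4.49) and Ccl20 (−4.30), had 1 more positive, 7 more negative and 14 not passing, the same adjusted over the list alone. The median was −1.03 (camera adjusted p = 0.00014, and adjusted p = 0.103 with an estimated correlation).

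Fetal-like genes, with Il1rn (−5.59 ± 0.52), Ccn2 (−5.14 ± 0.54) and Anxa8 (−3.56), had 0 more positive, 12 more negative and 7 not passing, and 1 and 14 adjusted over the list alone. Their median was −1.94 (camera adjusted p = 1.08e-09, and 0.025 with an estimated correlation). Colonocyte genes, with Cdhr5 (−4.62), Cdhr2 (−3.64) and Car1 (−3.15), had 0 more positive, 9 more negative and 5 not passing, and 0 and 10 adjusted over the list alone. The median was −1.93, or −1.21 without 3 members at 0 in a group (camera adjusted p = 3.36e-09, and 0.0236 with an estimated correlation). Junction genes, with Cldn1 (−4.26) and Krt19 (−3.16 ± 0.24), had 0 more positive, 9 more negative and 13 not passing, and 0 and 10 adjusted over the list alone. Their median was −0.70 (camera adjusted p = 1.44e-06, and adjusted p = 0.103 with an estimated correlation). Wnt targets, with Nkd1 (4.10), Dkk2 (3.21), Lef1 (2.95) and Wif1 (2.15), had 7 more positive, 2 more negative and 11 not passing, and 12 and 2 adjusted over the list alone. The median was 1.11 (camera adjusted p = 0.000168, and adjusted p = 0.103 with an estimated correlation). Proliferation genes had 12 more positive, 0 more negative and 20 not passing, and 19 and 0 adjusted over the list alone. Their median was 1.36 (camera adjusted p = 1.3e-08, and adjusted p = 0.294 with an estimated correlation). Ribosomal proteins, with Rpl13 (−2.02) and Rplp1 (−1.63), had 0 more positive, 17 more negative and 14 not passing, and 0 and 20 adjusted over the list alone. The median was −0.83 (camera adjusted p = 1.25e-10, and adjusted p = 0.236 with an estimated correlation). Cholesterol genes, with Acat2 (2.26) and Lss (1.43), had 6 more positive, 0 more negative and 19 not passing, and 10 and 0 adjusted over the list alone. Their median was 0.85 (camera adjusted p = 2.76e-05, and adjusted p = 0.368 with an estimated correlation). Pro-apoptotic genes, with Xaf1 (−2.50) and Bok (−1.87) down and Casp3 (1.71) up, had 3 more positive, 4 more negative and 22 not passing, with 4 and 4 adjusted over the list alone, and had no call by camera. Ripk3 (−1.31) was among 3 more negative pyroptosis and necroptosis genes, with 1 more positive and 17 not passing, in a list not called either.

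The other lists called by camera in the interaction were KRAS-ERK output, with Ereg (−5.46) and Fosl1 (−4.26; median −0.58, camera adjusted p = 0.000224, and adjusted p = 0.103 with an estimated correlation), and integrated stress, with Atf4 (−2.63; median −1.15, camera adjusted p = 0.00752, and adjusted p = 0.455 with an estimated correlation). MYC and ribosome biogenesis had a median of −0.93 (camera adjusted p = 0.000653, and adjusted p = 0.579 with an estimated correlation). Hypoxia and glycolysis, with Pdk1 (1.86), had a median of 0.61 (camera adjusted p = 0.00753, and adjusted p = 0.587 with an estimated correlation; 0.0855 without library 2 of the knockout with IFNg), and oxidative phosphorylation, with Ndufb8 (1.65), 0.19 (camera adjusted p = 0.027, and adjusted p = 0.659 with an estimated correlation; 0.2 without library 3 of control with IFNg, 0.117 without library 3 of the knockout and 0.0734 without library 2 of the knockout with IFNg).

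Across genes, the IFNg responses of the 2 genotypes had a low correlation. IFNg raised 221 genes in both, where independent lists would share 58.2, and lowered 121 in both, where 67.5 would be shared; 62 rose in control and fell in the knockout, against 60.2 for independent lists, and 81 went the other way, against 65.3. Over 12849 genes, which are not independent of each other, Pearson's r between the responses was 0.283 and Spearman's rho 0.002. For knockout against control without and with IFNg, 367 genes were higher in both and 258 lower in both, where independent lists would share 184.1 and 69.3, with r = 0.315 and rho = 0.200. Jackknife errors of r were 0.061 for the IFNg responses and 0.043 for knockout against control, and whether the 2 correlations differ was not tested.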

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

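The tests of 7 explanations below were chosen after the results were seen; the splits of the libraries were planned before. The IFNg response differed between the genotypes by limma's interaction test for 1006 genes more positive and 968 more negative in the knockout. Of genes named in advance, Myc (−1.81), Ifngr1 (−1.84), Ifngr2 (−0.88), Cxcl10 (−4.32) and Ido1 (−4.64) differed, as did, by size, Gzma (6.69), Psmb8 (5.53), Lypd2 (4.82), Def6 (4.80), Zfp503 (4.42), Hacd4 (4.35), Areg (−9.39), Slpi (−6.67), Sprr2h (−6.65), Prss2 (−6.57), Ly6g (−6.47) and Cxcl11 (−6.44). Of these, Ifngr1 and Ifngr2 lost the call on leaving out some single libraries (adjusted p up to 0.0969 and 0.0911), and Psmb8 was at −1.71 by edgeR. Gzma, Psmb8, Ido1 and Cxcl11 were at 0 in untreated control, so the size of their values rests on the added 1 CPM. Lists that differed at the preset correlation, with their medians, were IFNg response core (−0.27), type I interferon-associated (−2.21), MHC class I (0.60), MHC class II (2.19), Wnt target (1.11), fetal-like (−1.94), colonocyte (−1.93), proliferation (1.36), MYC and ribosome biogenesis (−0.93), NF-kB (−1.03), integrated stress (−1.15), hypoxia (0.61), KRAS-ERK output (−0.58), cholesterol (0.85), oxidative phosphorylation (0.19), junction (−0.70) and ribosomal proteins (−0.83). With an estimated correlation 2 of these 17 kept a call, fetal-like (adjusted p = 0.025) and colonocyte (adjusted p = 0.0236), and the others had an adjusted p = 0.103 to 0.659. Without members at 0 in a group the core median was 0.37, and by edgeR the MHC class II median was −0.79.

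The first pattern is that type I interferon-associated genes such as Rsad2, Ifit3 and Oasl1 rose less with IFNg in the knockout (19 of 30, adjusted p = 0.103 with an estimated correlation). A weaker IFNg response as a whole would lower the core and MHC class I genes too, but the 54 of these outside the type I list had a median interaction of 0.15 against −2.21 for the type I list (permutation p = 1e-05, the smallest that 1e5 permutations can give, across genes that are not independent). The log2(CPM + 1) scale alone would not leave the pattern on edgeR's ratio scale, but over the 21 members with reads in every group the edgeR median was −1.61 against −1.92 by limma, with 7 more negative and 0 more positive, though over the 9 with at least 1 CPM in both untreated groups it was a smaller −0.84 against −0.59, with 4 and 0. For the 9 members at 0 in untreated control a ratio of responses is unbounded, but with IFNg 7 were lower in the knockout and 0 higher by edgeR, with a median of −2.87. A need for Brd4 in the antiviral arm stays open as a hypothesis, beside a difference between the cell populations that carry the guides, which these libraries do not test.

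The second pattern is that fetal-like and colonocyte genes such as Il1rn, Ccn2 and Car1 fell with IFNg in the knockout. If the libraries named knockout with IFNg came from control organoids, genes silent in 1 untreated genotype would not keep their difference, but for 89% of 91 such genes the treated groups' means differed the same way. Replacement of epithelium by stromal or immune cells would bring their abundant transcripts, but the highest of 27 such markers was Cd68 at 3.23 CPM; Gzma, outside those lists, was at 170 CPM with Ptprc at 0.257 and Cd3e at 0 CPM. It would also lower epithelial genes alike, yet Epcam (0.44), Cdh1 (0.00) and Krt18 (0.04) stayed apart from Krt19 (−3.57) and Krt8 (−1.69), and the 22 junction genes, 9 lower and 0 higher, had a median of −0.68 against −1.85 for the 33 pattern genes. Open and untested are a role of Brd4 in keeping these genes on under IFNg, a shift in which epithelial cells survive, and an effect of a single clone.

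The third pattern is that Cdkn2a and Cdkn2b were near silent in the knockout with and without IFNg. A deletion reaching the neighbouring gene Mtap would lower it, but Mtap was at 108% of control without IFNg and 163% with it. Over 6 knockout libraries Cdkn2a and Cdkn2b had 38 reads, against 7476 and 8568 over the 7 control libraries, so a deletion of these genes alone and a loss of their transcription cannot be told apart, since so few reads could be misplaced ones. A Brd4 effect and a change carried by a clone stay open, untested.

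Chance was examined by regrouping libraries and counting changed genes. Of 35 splits of knockout and control libraries, the real one gave 1928 genes and the next 270. Of 35 for control with IFNg and control, these were 1628 and 217. This excludes a chance split, not chance differences between cultures. For the interaction 1 of 100 splits drawn from 700 gave as many, the real 1974 against 1082, so chance is excluded there too. For knockout with IFNg against knockout (1983, next 0) and against control with IFNg (3195, next 3), 10 splits are too few for a share under 0.05.

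In the control group, the only one of 4 libraries, 16 of 227 genes had 1 library far from the other 3, where chance gives about 1 in 20; of 6 library measures 0 did. The gap as a share of the range was, with library 1 high, 0.909 for Myc, 0.851 for Stat1, 0.849 for Apaf1, 0.875 for Gdf15, 0.838 for Ereg, 0.857 for Atf3, 0.956 for Sesn2, 0.960 for Def6 and 0.878 for Rnf43, and with library 1 low, 0.904 for Cox5b. It was 0.889 for Parp14, 0.861 for Rrm1 and 0.903 for Fabp4 with library 4 high, 0.939 for Rnf186 with library 2 high, and 0.907 for H1f5 and 0.836 for Naip1 with library 3 high.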

How the results depend on the processing

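The alternatives with thinned reads, with scaling to listed genes without Rn18s, and with 2 libraries left out together were chosen after the data were seen; the others were planned. With 3 or 4 libraries a group, the interaction finds few 2-fold changes, as the simulated data show, and the read depth differs between the groups: thinned to the smallest library, knockout against control gave 1151 higher and 709 lower genes. Of the counts of changed genes under all alternatives, 239 stayed within 1.5 times and 19 did not; of named gene values 13648 kept direction and side of the threshold, 1093 lost the call, 77 gained it, 33 without a call moved and 8 reversed; of list values 2977 kept both, 100 lost the call, 61 gained it, 94 moved and 3 reversed. The cause was not tested except where fewer genes or libraries make it plain.

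Array weights, which gave library 1 of the knockout with IFNg the lowest weight, 0.272, raised the counts to 2043 higher and 1342 lower for knockout against control, 1821 and 1816 for knockout with IFNg against knockout, and 1715 and 1516 for the interaction. Fits of only the groups compared gave 1127 lower for knockout against control, and 962 higher and 709 lower for knockout with IFNg against control with IFNg. Without a filter, which tests more genes, 519 were lower in control with IFNg and 616 more positive in the interaction. By edgeR 567 were lower in control with IFNg and 1268 higher in knockout with IFNg against control with IFNg. With the replicate number as a block, the counts were 905 and 543, 645 and 647, 889 and 943, 1803 and 1122, and 847 and 853 in the order of the comparisons, all within 1.5 times, and the IFNg response core lost its interaction call (adjusted p = 0.0515). An estimated correlation left 0, 5, 5, 3 and 2 lists with a call, of 10, 17, 13, 17 and 17. The correlation of the IFNg responses was 0.346 at a mean of at least 5 CPM. Scaled without Rn18s, 889 genes were higher and 1072 lower in the knockout.

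On leaving out 1 library, the counts ran from 781 to 1453 higher and 462 to 924 lower for knockout against control, from 469 to 1159 lower for control with IFNg, and from 629 to 1161 higher for knockout with IFNg against knockout. Interaction values that reversed, by edgeR and by DESeq2, were those of Psmb8 (−1.71 and −0.31), H2-Aa (−3.41 and −2.01), H2-Ab1 (−2.26 and −2.31) and Bcas1 (−3.40 and −2.58), each with a group at or near 0. The colonocyte list turned to −0.94 in knockout against control at a mean of at least 5 CPM, where fewer of its genes are tested. The hypoxia list of knockout with IFNg against knockout ran from −0.28 to 0.22 on leaving out 1 library and was 0.22 without library 3 of control with IFNg and library 1 of the knockout with IFNg together.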

Other observations

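The genes of these paragraphs outside the fixed rule were chosen after their values were seen. Sox2, a factor of foregut and stem cells, was at 15 ± 7.28 CPM in the knockout and 68.6 ± 15.2 CPM with IFNg (SD, n = 3 each), against 0.128 and 0.0854 CPM in control. The intestinal factor gene Cdx2 was at 60.5 ± 16.1 CPM in control (SD, n = 4), 29.9 ± 5.56 in the knockout, 59.6 ± 21.7 in control with IFNg and 2.57 ± 3.96 in the knockout with IFNg (SD, n = 3 each). Cdx1 was at 0 CPM in control, 8.24 ± 0.737 in the knockout (SD, n = 3) and under 0.1 CPM in both IFNg groups. Hoxa10 went with Hoxa9, from 21.8 to 0.00813 CPM, as did Hoxa11 (2.2 to 0 CPM) and Hoxa13 (8.43 to 0.686 CPM), while Evx1, next in the cluster on chromosome 6, was at 13.8 and 23.6 CPM.

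Within the MHC region Psmb8 (17:34416695-34420428) was at 0, 1.16, 17.1 and 1660 CPM in control, knockout, control with IFNg and knockout with IFNg. Between the treated groups other genes there also had higher means in the knockout, such as H2-Aa (70.2 to 1260 CPM), H2-DMb2 (0.336 to 8.3 CPM) and H2-Eb2 (0.033 to 4.03 CPM). The neighbouring Psmb9 was at 1.71, 0.49, 182 and 385 CPM in the same order of groups, Tap1 at 2.96, 1.29, 118 and 179 CPM, and Tap2 at 3.85, 0.954, 26.5 and 86.1 CPM. Psmb8 overlaps Gm20496, which was at most 0.622 CPM in any library. Gzma was at 170 ± 62.7 CPM in the knockout with IFNg (SD, n = 3), with Ptprc at 0.257 CPM.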
